A study of Astyanax mexicanus with 12 samples.

How the data were processed

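Poly(A) RNA of 12 livers of adult Astyanax mexicanus was measured, 3 from each of 4 groups: wild-caught cave fish (titled Pachón), laboratory cave fish, wild-caught surface fish and laboratory surface fish. Per the labels' protocols, the fish were fasted for 12 hours before dissection, stranded mRNA libraries were made with a TruSeq kit, and single reads of 75 nt were sequenced on an Illumina NextSeq instrument. Sex, age and body size of the fish, the date of each capture and any sequencing batch are not given in the sources used here.

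The deposited table holds TPM, a length-scaled transcript abundance, for each Ensembl gene and library, estimated by the authors with RSEM, per the file name and the labels' list of tools. Per the labels, reads were demultiplexed with bcl2fastq 2.18 and aligned with STAR 2.6.1c. The version of RSEM, the genome build, the annotation release and any filter on genes are not given in the sources used here, so no coordinates are printed. Each column was checked and sums to the total of a TPM table within rounding. TPM divides by transcript length and by the total of the library and keeps no depth, so the number of reads behind each value is unknown. All 12 columns were mapped to a sample by group and replicate number. Gene names were taken from the table itself, which names 18362 genes; 1341 of these share a name with another gene and are left out of the named examples. The reference table of gene symbols that came with the data has no column that joins these Ensembl identifiers, and it was not used.

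Genes at 1 TPM or more in at least 3 of the 12 libraries were tested, which left 12895, of which 2582 have no name. Values were analysed as log2(TPM + 1) in R 4.3.3 with limma 3.58.1. A linear model with 4 group means was fitted to all 12 libraries, and moderated standard errors came from eBayes with a trend on the mean. The 5 contrasts were cave minus surface in wild-caught and in laboratory fish, wild-caught minus laboratory in cave and in surface fish, and the difference between the morphotype contrasts (the interaction). Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each contrast, with 0.05 as the threshold. The model, the filter, the threshold, the gene lists, the naming rule and most alternatives were chosen before the data were examined.

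Because TPM values of a library must sum to a fixed total, abundant genes push all others down. The counts of called genes, and of genes without overlap between groups, were therefore also computed with median-of-ratios factors, which centre each library on the genes above 0 in all libraries. Changes of gene lists are given relative to the median of all tested genes in the same contrast.

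Expression was summarised over 40 fixed gene lists, 25 for pathways and complexes and 15 for cell types that a fish liver sample may hold, matched by gene symbol without regard to case. Of these, 35 had at least 5 tested members and were tested with camera in limma, at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 35 lists within each contrast. Camera compares a list with the other genes. Fry, also in limma, tests whether a list's genes move in a common direction, without comparing them with other genes. The pattern for ribosomal protein genes also caught rps6kl1, which was kept as the list was fixed.

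Named genes follow a fixed rule. In each contrast of 2 groups, these are the 8 largest rises and the 8 largest falls among genes past the threshold with a symbol, a log2 difference of at least 1, a mean of at least 10 TPM in the higher group and no overlap between the libraries of the groups. To these were added the called members with the smallest adjusted p of each list that passed or held at least 3 called members, and, where no member passed, up to 2 members with the highest mean TPM. For the interaction the 5 largest in each direction were taken, without the condition on overlap. The texts give a selection of these genes.

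The share of variance due to morphotype and environment was taken from sums of squares over all tested genes, with an exact permutation of 400 label orders each. Agreement between contrasts that share no library was described across genes. Genes listed at 0 in all 6 libraries of a morphotype and at 1 TPM or more in all 6 of the other were counted and compared with all 462 splits of the 12 libraries. Whether equal replicate numbers mark shared batches was checked by correlating the residuals of libraries with the same number. Of 18 such correlations, which ranged from -0.207 to 0.271, 4 were above 0.1, and the surface wild and surface lab groups alone had all 3 above it (0.153, 0.111 and 0.271). The surface comparison is therefore also given with the replicate number as a block.

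The alternatives were median-of-ratios and quantile scaling, removal of the 50 most abundant genes, a pseudocount of 0.1, no filter, a filter at 5 TPM, the replicate block, a fit of only the 6 libraries compared, robust eBayes, array weights, a minimum log2 difference of 1, and leaving out each library in turn. Alternatives chosen after seeing the data were a fit without surface wild libraries 1 and 2, vtg3 as a covariate, removal of ribosomal protein genes with rescaling to the fixed total, and the replicate block in the 6 surface libraries alone.

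The scripts were tested on simulated data with the overall mean and the pooled residual spread of each of the 12895 genes. In these data 50 genes above 10 TPM were changed at each of 4 sizes. In the comparison of wild-caught cave and surface livers, 3 of 50 genes changed by a log2 difference of 1 were recovered, 27 at 2, 37 at 3 and 48 at 4, with 6 unchanged genes called. For laboratory cave and surface livers these numbers were 3, 24, 41 and 47, with 6 unchanged genes called. For wild-caught and laboratory cave livers they were 1, 28, 40 and 46, with 5 unchanged, and for surface livers 1, 23, 41 and 48, with 2 unchanged. For the interaction they were 0, 7, 33 and 42, with 8 unchanged, so differences of a log2 size of 1 mostly went uncalled in these simulated data. Only 200 genes were changed in them, which makes the adjusted threshold stricter than where many genes are called. Of the 4074 genes called between wild-caught forms, 3172 had a log2 difference of at least 1, so smaller ones were called as well. A list shifted as a whole in the simulated wild-caught and laboratory cave livers was called by camera (adjusted p = 2.1e-63), and 0 of the other lists passed. Each gene had the same spread in all simulated libraries. In the real libraries estimated array weights, lower for libraries with more scatter, ran from 0.319 to 3.51. The numbers of unchanged genes called therefore do not show the error rate where groups differ in spread. Genes were also drawn independently of each other in the simulated data. The simulation therefore does not show how often lists of correlated genes pass by chance at the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.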

Results

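RNA was sequenced from 12 livers of adult Astyanax mexicanus, a fish with a blind cave form and a sighted surface form. Wild-caught and laboratory fish of both forms were sampled after 12 hours of fasting, 3 livers in each of 4 groups: cave wild, cave lab, surface wild and surface lab. The questions were how liver expression differs between the forms in each environment, how it differs between wild-caught and laboratory fish of each form, and whether these differences depend on each other. The table held TPM (transcript abundance scaled to the same total in each library) for 27420 genes, of which 4572 were listed at 0 in every library and 12895 were tested. TPM keeps no depth, so the read number behind each value is unknown. Levels are means ± SD in TPM with n = 3 livers, and differences are log2 differences ± standard error from limma with p adjusted within each comparison.

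Wild-caught cave livers put a larger share of their transcripts into ribosomal protein genes than all other livers, 35.7 ± 1.87% (n = 3), against 20.4 ± 3.34% in cave lab, 22.0 ± 1.96% in surface wild and 14.7 ± 2.88% in surface lab livers. They also expressed fewer genes at 1 TPM or more, 9718 ± 498, against 12029 ± 273 in cave lab, 10978 ± 61.5 in surface wild and 11330 ± 424 in surface lab livers. This count depends on the TPM scale. The mean median-of-ratios factor was 0.66 in cave wild, 1.28 in cave lab, 1.06 in surface wild and 1.19 in surface lab livers. Over all tested genes, morphotype accounted for 24.9% of the variance and environment for 27.6% (exact permutation p = 0.005 each, the smallest attainable with 400 orders). Their interaction held 13.8%, and 33.7% was residual. Environment here means wild-caught against laboratory fish, and the design cannot separate surroundings from any difference in stock or ancestry. Any difference in place or conditions of capture between wild-caught cave and surface fish goes with form. It cannot be separated from form in the wild-caught comparison or in the interaction. Spearman correlations ran from 0.811 to 0.947 within groups and from 0.566 to 0.874 between them. Surface wild libraries 1 and 2 lay apart on the first component, at -113 and -101 against -37.3 for library 3.

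**Figure D1:**
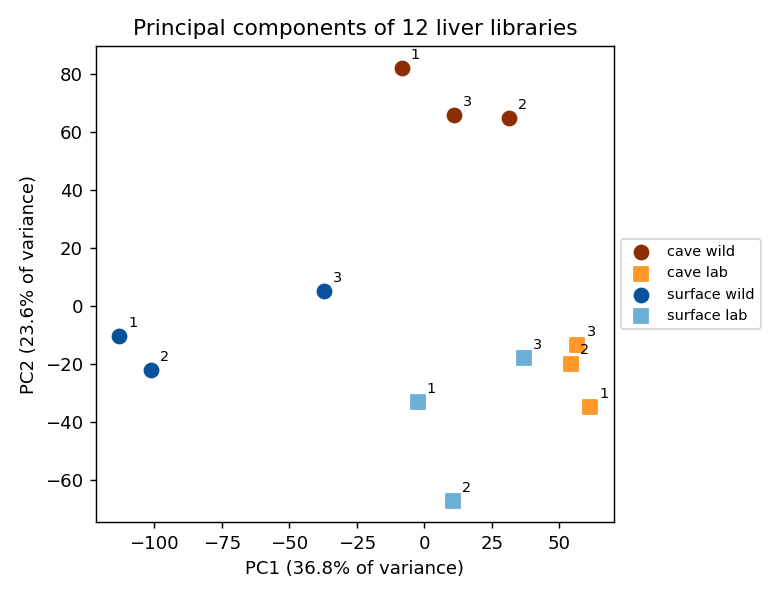
Scores of the 12 livers on the first and second principal components of log2(TPM + 1), in arbitrary units with the share of variance on each axis. Colours stand for the 4 groups and numbers for the replicate; surface wild livers 1 and 2 lie lowest on the first component, apart from liver 3 of their group.

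Most sterol synthesis and unfolded protein response genes were lower in wild-caught cave than in wild-caught surface livers, and most ribosomal protein genes were higher. The endoplasmic reticulum chaperone hspa5 (ENSAMXG00000009012) stood at 25.1 ± 23.2 TPM in cave and 1446 ± 567 in surface livers (log2 difference -6.12 ± 0.96, adjusted p = 0.00313). Haptoglobin, hp, which binds free haemoglobin, stood at 214 ± 138 and 11556 ± 5931 TPM (-5.76 ± 0.53, adjusted p = 1.4e-04). The rate-limiting enzyme of cholesterol synthesis, hmgcra, stood at 2.1 ± 3.60 and 94.4 ± 84.8 TPM (-5.08 ± 0.83, adjusted p = 0.00346). The cerebellin family gene cbln5 (ENSAMXG00000029540) was listed at 0 in all 3 cave livers and stood at 267 ± 123 TPM in surface livers. Apolipoprotein E, apoeb, was at 165 ± 165 and 3839 ± 1907 TPM (-5.02 ± 0.82, adjusted p = 0.00361). Higher in cave livers was fam20cl, of a family of secreted kinases, at 742 ± 66.8 against 15.3 ± 9.86 TPM (5.66 ± 0.68, adjusted p = 6.7e-04). The gene fam20cl is also on the list of egg yolk precursors and oestrogen-responsive genes, and the sex of the fish is not given. Hepatic lipase lipca (4.88 ± 0.90, adjusted p = 0.00561) and sarcosine dehydrogenase sardh (4.08 ± 0.73, adjusted p = 0.00522) were higher as well.

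Sterol synthesis differed as a group in wild-caught fish: its list gave 20 lower and 5 not passing of 25 tested (21 lower adjusted over the list alone). Among the lower genes were msmo1 (-4.80 ± 0.83) and hmgcs1 (-4.12 ± 0.73). In surface wild 1, 2 and 3 msmo1 stood at 263, 58.1 and 14.3 TPM, against 0.39 to 4.44 in cave wild livers. For hmgcs1 these values were 501, 88.9 and 59.3, against 3.85 to 10.15. The median of the list minus that of all genes, here called the relative median, was -2.45 (camera adjusted p = 1.1e-05; adjusted p = 0.558 with an estimated correlation). The unfolded protein response, which raises folding capacity in the secretory pathway, gave 33 lower and 13 not passing of 46 tested (37 lower adjusted over the list alone), with dnajb9b (-4.84 ± 0.63) and derl2 (-2.38 ± 0.37) lower. Its relative median was -1.95 (camera adjusted p = 4.6e-07; adjusted p = 0.558 with an estimated correlation). The proteasome, which degrades tagged proteins, gave 29 lower and 10 not passing of 39 tested (31 lower adjusted over the list alone), with psmd11b (-2.45 ± 0.56) and psmd6 (-2.32 ± 0.53) lower. Proteasome genes had a relative median of -1.32 (camera adjusted p = 5.1e-05; adjusted p = 0.768 with an estimated correlation). Macrophage markers gave 11 lower and 7 not passing of 18 tested (11 lower adjusted over the list alone), with the iron exporter slc40a1 (-2.19 ± 0.45) lower. Their relative median was -0.69 (camera adjusted p = 0.0113; adjusted p = 0.558 with an estimated correlation). Under median-of-ratios scaling 6 proteasome genes and 3 macrophage markers stayed lower.

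Ribosomal protein genes lay on the other side in wild-caught cave livers, with 52 higher, 1 lower and 28 not passing of 81 tested (70 higher and 1 lower adjusted over the list alone). An example was rps19 (1.17 ± 0.22), and the relative median was 1.16 (camera adjusted p = 1.2e-34; adjusted p = 0.394 with an estimated correlation). Amino acid catabolism gave 10 higher, 4 lower and 58 not passing of 72 tested (9 higher and 2 lower adjusted over the list alone), with hgd of tyrosine breakdown (2.88 ± 0.40) and got2a (2.85 ± 0.52) higher. Catabolic genes had a relative median of 0.94 (camera adjusted p = 4.8e-10; adjusted p = 0.253 with an estimated correlation). Xenobiotic metabolism gave 7 higher, 1 lower and 19 not passing of 27 tested (6 higher and 1 lower adjusted over the list alone), with cyp1a (3.43 ± 0.65) and cyp2u1 (3.28 ± 0.75) higher. This list's relative median was 1.17 (camera adjusted p = 1.6e-08; adjusted p = 0.253 with an estimated correlation). Egg yolk precursors and oestrogen-responsive genes gave 3 higher and 5 not passing of 8 tested (3 higher adjusted over the list alone) and a relative median of 1.67 (camera adjusted p = 4.8e-05; adjusted p = 0.253 with an estimated correlation). Clock genes gave 3 higher, 3 lower and 37 not passing of 43 tested (2 higher and 2 lower adjusted over the list alone) and a relative median of 0.59 (camera adjusted p = 0.00191; adjusted p = 0.377 with an estimated correlation).

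Fatty acid oxidation genes and hepatocyte markers passed as higher than other genes in wild-caught cave livers, yet their mean log2 differences were -0.000944 and -0.00282 and their medians -0.01 and 0.30. Fatty acid oxidation gave 2 higher, 3 lower and 38 not passing of 43 tested (1 lower adjusted over the list alone) and a relative median of 0.45 (camera adjusted p = 0.0247; adjusted p = 0.773 with an estimated correlation). Hepatocyte markers gave 4 higher, 6 lower and 13 not passing of 23 tested (4 higher and 6 lower adjusted over the list alone) and a relative median of 0.76 (camera adjusted p = 0.0423; adjusted p = 0.394 with an estimated correlation). Erythrocyte and thrombocyte markers gave 2 higher, 2 lower and 11 not passing of 15 tested (2 higher and 2 lower adjusted over the list alone) and a relative median of 0.66 (camera adjusted p = 0.0402; adjusted p = 0.558 with an estimated correlation).

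Fatty acid oxidation lost its wild-caught call without cave wild 1 (adjusted p = 0.0790), surface wild 1 (0.424) or surface wild 2 (0.0876), and under median-of-ratios scaling (0.082). Erythrocyte markers lost it without cave wild 2 (0.0651), cave wild 3 (0.0534) or surface wild 2 (0.0884), and under median-of-ratios scaling (0.089). Hepatocyte markers lost it without cave wild 3 (0.0960), surface wild 1 (0.0701) or surface wild 2 (0.0793). Other lists held called members in wild-caught fish without passing, where 3413 of all 12895 tested genes were called lower. Complement gave 1 higher, 11 lower and 9 not passing of 21 tested (2 higher and 13 lower adjusted over the list alone), with c9 (-2.28 ± 0.33) and c7b (-6.85 ± 1.25) of the membrane attack complex lower. Acute phase and inflammation gave 1 higher, 7 lower and 12 not passing of 20 tested (1 higher and 7 lower adjusted over the list alone), with the receptor il6r (-1.95 ± 0.35) and its transducer stat3 (-2.90 ± 0.62) lower. Coagulation gave 1 higher, 6 lower and 16 not passing of 23 tested (6 lower adjusted over the list alone), with f5 lower (-2.58 ± 0.49). The hypoxia response gave 1 higher, 6 lower and 25 not passing of 32 tested (5 lower adjusted over the list alone), with epas1b lower (-1.96 ± 0.32). Under median-of-ratios scaling 6, 4, 2 and 3 genes of these 4 lists were lower and 4, 1, 2 and 3 higher.

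In total 4074 genes passed in wild-caught fish, 661 higher and 3413 lower in cave livers, while the median log2 difference of all genes was -0.46. Median-of-ratios scaling, which takes out this shift, gave 2327 genes, 1296 higher and 1031 lower, so the excess of lower genes depends on the scaling. Leaving out cave wild 1, 2 or 3 gave 2705, 1710 or 2357 genes, and leaving out surface wild 1, 2 or 3 gave 1742, 1546 or 5162. Without both surface wild 1 and 2 the count was 226, and with vtg3 as a covariate 141. The 6 wild-caught livers fitted alone gave 1916. Quantile scaling kept 9 of the 12 list calls. Libraries of the groups did not overlap for 5778 genes (44.8%), and for 4193 (32.5%) with median-of-ratios scaling, where 10% is the share by chance.

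**Figure D2:**
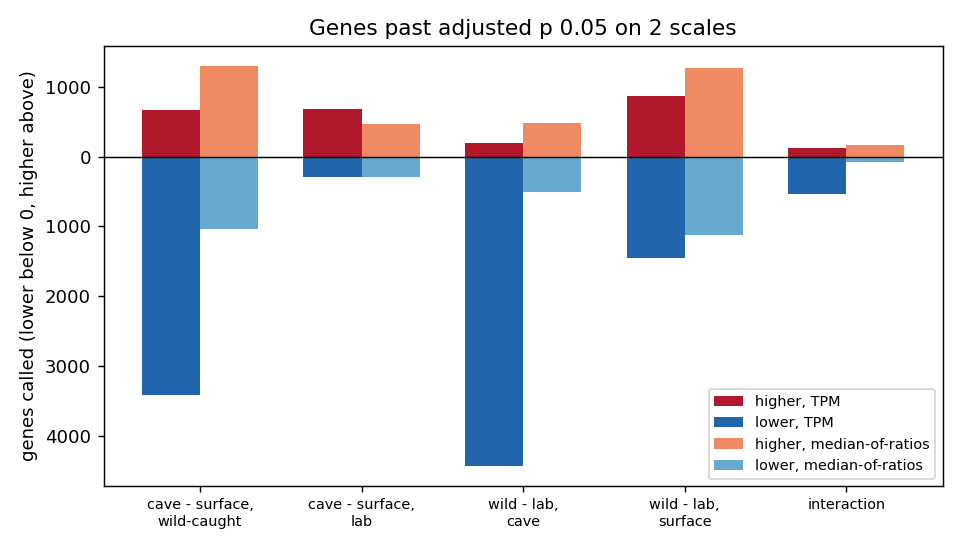
Number of genes passing in limma in each of the 5 comparisons, higher above and lower below 0. Colours stand for TPM and for median-of-ratios scaling; with TPM far more genes are lower than higher in wild-caught cave livers, and with median-of-ratios scaling the numbers are closer.

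Laboratory cave and surface livers differed in several genes that were nearly off in a single form. Glutamate dehydrogenase glud1a (ENSAMXG00000021266) was close to absent in cave livers, at 0.0467 ± 0.0808 against 264 ± 49.4 TPM (-7.97 ± 0.43, adjusted p = 7.0e-07). Hepatic lipase lipca stood at 0.71 ± 0.332 against 81.0 ± 40.7 TPM (-5.45 ± 0.90, adjusted p = 0.00278). The gene cbln5 was again nearly confined to surface livers (-8.50 ± 0.61, adjusted p = 7.0e-06). Higher in cave livers was the tyrosine breakdown enzyme hpdb, at 150.1 ± 25.3 against 4.65 ± 7.70 TPM (5.76 ± 0.74, adjusted p = 4.5e-04). The sulphate transporter slc13a4 stood at 46.7 ± 9.16 against 0.273 ± 0.156 TPM (5.22 ± 0.21, adjusted p = 6.8e-08). The kinesin kif1ab (4.53 ± 0.55), the serpin serpine3 (4.04 ± 0.55) and smpx (3.83 ± 0.42) were higher in cave livers. The inositol oxygenase miox (-5.15 ± 1.06) and the fatty acid binding protein fabp11a (-4.20 ± 0.78) were lower.

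Antiviral genes were a group that stood higher in laboratory cave livers: the interferon response gave 5 higher and 27 not passing of 32 tested (16 higher adjusted over the list alone), with mxf (1.86 ± 0.35) higher. Interferon genes had a relative median of 1.07 (camera adjusted p = 9.8e-06; adjusted p = 0.853 with an estimated correlation). The circadian clock gave 7 higher and 36 not passing of 43 tested (11 higher adjusted over the list alone), with per3 at 20.2 ± 4.23 against 2.503 ± 2.38 TPM (2.86 ± 0.52). The hour of dissection was not in the model, and its part in clock differences was not tested in any comparison. Clock genes had a relative median of 0.59 (camera adjusted p = 0.00212; adjusted p = 0.853 with an estimated correlation), and they alone also passed in fry (adjusted p = 0.0138). Macrophage markers gave 2 higher, 1 lower and 15 not passing of 18 tested (7 higher and 1 lower adjusted over the list alone) and a relative median of 0.79 (camera adjusted p = 0.00296; adjusted p = 0.853 with an estimated correlation). Ribosomal proteins gave 1 higher and 80 not passing of 81 tested (0 adjusted over the list alone) and a relative median of 0.37 (camera adjusted p = 1.0e-08; adjusted p = 0.874 with an estimated correlation).

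Proteasome genes lay lower in laboratory cave livers as a list, with 0 of 39 tested passing in limma, with 14 at an unadjusted p under 0.05 (0 adjusted over the list alone). Their relative median was -1.19 (camera adjusted p = 4.3e-10; adjusted p = 0.853 with an estimated correlation). In fry the proteasome list did not pass (adjusted p = 0.298). Its member psmd6 stood at 163, 121 and 42.3 TPM in surface lab 1, 2 and 3, and at 38.3 to 47.4 in cave lab livers. For psmb1 these values were 299, 341 and 76.7, against 85.2 to 107. Exocrine pancreas markers gave 2 lower and 7 not passing of 9 tested (2 lower adjusted over the list alone), with the lipase PNLIPRP2 (-4.60 ± 0.86) and cuzd1.2 (-1.89 ± 0.37) lower. Exocrine markers had a relative median of -1.997 (camera adjusted p = 1.2e-04; adjusted p = 0.853 with an estimated correlation). Heat shock had 0 of 32 tested passing in limma, with 5 at an unadjusted p under 0.05 (0 adjusted over the list alone) and a relative median of -0.55 (camera adjusted p = 0.00679; adjusted p = 0.874 with an estimated correlation). Lipoproteins and lipid transport gave 2 lower and 23 not passing of 25 tested (2 lower adjusted over the list alone) and a relative median of -0.36 (camera adjusted p = 0.0366; adjusted p = 0.853 with an estimated correlation). Oxidative phosphorylation gave 2 higher and 83 not passing of 85 tested (2 higher adjusted over the list alone) and a relative median of -0.27 (camera adjusted p = 0.0373; adjusted p = 0.907 with an estimated correlation). Its called members cox4i1l (2.55 ± 0.39) and cox6b1 (3.40 ± 0.70) were opposite in sign to the list.

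Lipoproteins lost this laboratory call without cave lab 2 (adjusted p = 0.106) or surface lab 3 (0.0677), heat shock without surface lab 1 (0.0649), and macrophage markers without surface lab 2 (0.0987). Oxidative phosphorylation lost it without cave lab 2 (0.150), surface wild 2 (0.0696), surface lab 1 (0.199) or surface lab 2 (0.0987). Cholesterol synthesis had 0 of 25 tested passing in limma, with 1 at an unadjusted p under 0.05 (0 adjusted over the list alone) in laboratory fish. The unfolded protein response gave 1 lower and 45 not passing of 46 tested (1 lower adjusted over the list alone). A total of 974 genes passed, 678 higher and 296 lower in cave livers, at a median log2 difference of 0.10 for all genes. Median-of-ratios scaling gave 767, 468 higher and 299 lower. Quantile scaling kept 7 of the 9 list calls. Without cave lab 3 the number was 635 and without surface lab 1 it was 614. Groups did not overlap for 3538 genes (27.4%, 10% by chance), and for 4067 (31.5%) with that scaling.

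Wild-caught cave livers expressed genes that were nearly off in laboratory cave livers, and lacked others that were on there. Hepatic lipase lipca (ENSAMXG00000012304) stood at 235 ± 40.3 TPM in wild-caught and 0.71 ± 0.332 in laboratory cave livers (7.11 ± 0.90, adjusted p = 9.0e-04). The enzyme glud1a stood at 111 ± 52.0 and 0.0467 ± 0.0808 TPM (6.64 ± 0.43, adjusted p = 9.8e-06). The mitochondrial isocitrate dehydrogenase idh2 (3.50 ± 0.74), the water channel gene aqp12 (3.98 ± 0.77) and the transcriptional inhibitor id2b (3.45 ± 0.52) rose too. Lower in wild-caught cave livers was hpdb, at 0.973 ± 0.736 against 150.1 ± 25.3 TPM (-6.31 ± 0.74, adjusted p = 7.1e-04). The transporter slc13a4 fell to 0.0833 ± 0.0611 from 46.7 ± 9.16 TPM (-5.44 ± 0.21, adjusted p = 8.2e-08). The transcription factor mlx stood at 3.39 ± 1.29 against 65.0 ± 53.8 TPM (-3.63 ± 0.51, adjusted p = 0.00144). The fatty acid transporter slc27a6 (-4.42 ± 0.76) fell as well.

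Most ribosomal protein genes were higher in wild-caught than in laboratory cave livers, with 69 higher, 1 lower and 11 not passing of 81 tested (74 higher and 1 lower adjusted over the list alone). RPL27A (0.93 ± 0.18) and rps15 (1.04 ± 0.22) were among them, and the relative median was 1.49 (camera adjusted p = 2.7e-81; adjusted p = 0.334 with an estimated correlation). Clock genes gave 25 lower and 18 not passing of 43 tested (29 lower adjusted over the list alone), the nuclear receptors roraa (-1.98 ± 0.31) and rorcb (-2.48 ± 0.41) among them. Clock genes had a relative median of -0.47 (camera adjusted p = 0.029; adjusted p = 0.831 with an estimated correlation), and 4 stayed lower under median-of-ratios scaling. Exocrine pancreas markers gave 1 higher and 8 not passing of 9 tested (1 higher adjusted over the list alone) and a relative median of 1.33 (camera adjusted p = 3.0e-05; adjusted p = 0.831 with an estimated correlation).

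Some lists passed as higher than other genes in wild-caught cave livers although their own medians were below 0 on the TPM scale. Oxidative phosphorylation gave 2 lower and 83 not passing of 85 tested (1 lower adjusted over the list alone), a median of -0.01 and a relative median of 0.68 (camera adjusted p = 1.9e-11; adjusted p = 0.971 with an estimated correlation). For heat shock genes, 2 higher, 5 lower and 25 not passing of 32 tested were found, with medians of -0.18 and 0.51 (camera adjusted p = 9.7e-04; adjusted p = 0.971 with an estimated correlation). Cholesterol synthesis gave 1 lower and 24 not passing of 25 tested, with medians of -0.29 and 0.39 (camera adjusted p = 0.0091; adjusted p = 0.971 with an estimated correlation). Cell cycle genes had 0 of 19 tested passing in limma, with 2 at an unadjusted p under 0.05, and medians of -0.18 and 0.51 (camera adjusted p = 0.0151; adjusted p = 0.831 with an estimated correlation). Unfolded protein response genes gave 1 higher, 7 lower and 38 not passing of 46 tested, with medians of -0.67 and 0.02 (camera adjusted p = 0.0476; adjusted p = 0.971 with an estimated correlation). Under median-of-ratios scaling the medians of oxidative phosphorylation and heat shock turned to 0.94 and 0.62.

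Other lists held called members in wild-caught against laboratory cave livers without passing as lists, where 4423 of all 12895 tested genes were called lower. The interferon response gave 18 lower and 14 not passing of 32 tested (21 lower adjusted over the list alone), with tap1 (-2.01 ± 0.31), parp9 (-1.96 ± 0.32) and stat1a (-2.68 ± 0.50) lower. Macrophage markers gave 9 lower and 9 not passing of 18 tested (12 lower adjusted over the list alone), with slc40a1 at 11.8 ± 2.28 against 133 ± 45.6 TPM (-3.33 ± 0.45). The hypoxia response gave 14 lower and 18 not passing of 32 tested (14 lower adjusted over the list alone), with epas1b lower (-2.18 ± 0.32). Amino acid catabolism gave 2 higher, 35 lower and 35 not passing of 72 tested (2 higher and 38 lower adjusted over the list alone), with bckdha of branched-chain breakdown lower (-3.05 ± 0.37). Insulin and growth factor signalling gave 12 lower and 22 not passing of 34 tested, complement 11 lower and 10 not passing of 21 tested, and fatty acid and triglyceride synthesis 1 higher, 11 lower and 21 not passing of 33 tested. The ferritin subunit fth1b, of the antioxidant list, was lower at 523 ± 102 against 2826 ± 527 TPM (-2.44 ± 0.36, adjusted p = 0.00164). Under median-of-ratios scaling few members of these lists stayed lower: 4 of the interferon response, 1 macrophage marker, 1 of the hypoxia response and 4 of amino acid catabolism. Insulin signalling and fat synthesis each kept 1 lower gene under that scaling.

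Of the 4618 genes that passed in cave fish, 195 were higher and 4423 lower in wild-caught livers, at a median log2 difference of -0.69 for all genes. Median-of-ratios scaling gave 983, 479 higher and 504 lower, so most lower calls depend on the scaling. Quantile scaling kept 5 of the 8 list calls. The 6 cave libraries fitted alone gave 6209 genes. Leaving out cave wild 1 gave 2179 genes, cave lab 1 2915 and cave lab 2 2856. The circadian list lost its call without cave wild 1 (adjusted p = 0.102), cholesterol synthesis without cave wild 2 (0.420) and under median-of-ratios scaling (0.27). The unfolded protein response lost it without cave wild 1 (0.661), cave lab 2 (0.136), cave lab 3 (0.0534), surface lab 1 (0.0507), surface lab 2 (0.213) or surface lab 3 (0.0752), and under median-of-ratios scaling (0.40). Groups did not overlap for 7710 genes (59.8%, 10% by chance), a share that holds the shift of all genes, and for 4930 (38.2%) with median-of-ratios scaling.

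Most sterol synthesis genes were higher in wild-caught than in laboratory surface livers, and most amino acid catabolism and xenobiotic metabolism genes were lower. The enzyme hmgcra (ENSAMXG00000007971) stood at 94.4 ± 84.8 TPM in wild-caught and 0.197 ± 0.206 in laboratory livers (5.80 ± 0.83, adjusted p = 0.00234). Haptoglobin, hp, stood at 11556 ± 5931 and 1155 ± 339.9 TPM (3.196 ± 0.53, adjusted p = 0.0045), and hspa5 at 1446 ± 567 and 121 ± 163 TPM (4.59 ± 0.96, adjusted p = 0.0112). Ornithine decarboxylase odc1, the entry to polyamine synthesis, was at 55.2 ± 25.6 and 1.4 ± 1.09 TPM (4.52 ± 0.43, adjusted p = 1.9e-04). The immunoproteasome subunit psmb8a was at 75.9 ± 30.8 and 2.41 ± 0.705 TPM (4.44 ± 0.54, adjusted p = 9.2e-04). The mitochondrial uncoupling protein ucp1 (ENSAMXG00000005590) fell, with 84.5 ± 55.1 against 4279 ± 2281 TPM (-5.76 ± 0.66, adjusted p = 6.5e-04). The cytochrome P450 genes cyp2u1 (-5.51 ± 0.75, adjusted p = 0.00181) and cyp8b2 of bile acid synthesis (-3.999 ± 0.57, adjusted p = 0.00244) fell as well.

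Sterol synthesis had the largest relative median of the lists in wild-caught surface livers, with 16 higher and 9 not passing of 25 tested (19 higher adjusted over the list alone). The median log2 difference of its genes from the laboratory mean was 4.46, 3.11 and 1.44 in surface wild livers 1, 2 and 3. Beside hmgcra stood msmo1 (5.15 ± 0.83) and sqlea (4.93 ± 0.83), and the relative median was 3.07 (camera adjusted p = 7.7e-12; adjusted p = 0.325 with an estimated correlation). The unfolded protein response gave 15 higher and 31 not passing of 46 tested (33 higher adjusted over the list alone), with hyou1 higher (4.03 ± 0.79), and this median was 1.80, 1.67 and 0.87 in the 3 livers. Its relative median was 1.49 (camera adjusted p = 1.3e-11; adjusted p = 0.325 with an estimated correlation). Ribosomal proteins gave 14 higher and 67 not passing of 81 tested (42 higher adjusted over the list alone) and a relative median of 0.68 (camera adjusted p = 5.0e-16; adjusted p = 0.341 with an estimated correlation). The interferon response gave 6 higher and 26 not passing of 32 tested (6 higher adjusted over the list alone), with psmb13a higher (2.80 ± 0.38). Interferon genes had a relative median of 0.77 (camera adjusted p = 6.4e-04; adjusted p = 0.422 with an estimated correlation).

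Further lists passed as higher than other genes in wild-caught surface livers. Macrophage markers gave 5 higher, 1 lower and 12 not passing of 18 tested (9 higher and 1 lower adjusted over the list alone) and a relative median of 0.97 (camera adjusted p = 6.4e-04; adjusted p = 0.325 with an estimated correlation). Neutrophil markers gave 2 higher and 4 not passing of 6 tested (4 higher adjusted over the list alone) and a relative median of 1.16 (camera adjusted p = 0.00643; adjusted p = 0.325 with an estimated correlation). Cell cycle genes gave 5 higher and 14 not passing of 19 tested (6 higher adjusted over the list alone) and a relative median of 0.61 (camera adjusted p = 0.00268; adjusted p = 0.325 with an estimated correlation). Glycolysis gave 3 higher, 1 lower and 20 not passing of 24 tested (3 higher and 1 lower adjusted over the list alone) and a relative median of 0.69 (camera adjusted p = 0.0231; adjusted p = 0.325 with an estimated correlation). Heat shock had 0 of 32 tested passing in limma, with 7 at an unadjusted p under 0.05 (0 adjusted over the list alone) and a relative median of 0.54 (camera adjusted p = 0.0402; adjusted p = 0.714 with an estimated correlation).

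Several lists passed as lower than other genes in wild-caught surface livers, though not with an estimated correlation. Amino acid catabolism gave 1 higher, 39 lower and 32 not passing of 72 tested (1 higher and 48 lower adjusted over the list alone), with gls2b (-2.99 ± 0.39), qdpra (-2.30 ± 0.31) and tdo2b (-3.30 ± 0.49) lower. Its relative median was -1.47 (camera adjusted p = 6.2e-11; adjusted p = 0.325 with an estimated correlation). Xenobiotic metabolism gave 1 higher, 15 lower and 11 not passing of 27 tested (1 higher and 17 lower adjusted over the list alone), with ugt1b2 lower (-3.39 ± 0.48). This list's relative median was -1.43 (camera adjusted p = 2.9e-05; adjusted p = 0.325 with an estimated correlation). Fatty acid oxidation gave 11 lower and 32 not passing of 43 tested (14 lower adjusted over the list alone), with acadm lower (-2.88 ± 0.56). Oxidation genes had a relative median of -1.14 (camera adjusted p = 7.2e-05; adjusted p = 0.422 with an estimated correlation). Gluconeogenesis and glycogen gave 1 higher, 7 lower and 23 not passing of 31 tested (1 higher and 10 lower adjusted over the list alone), with gyg2 (-3.69 ± 0.56) and fbp1a (-2.08 ± 0.34) lower. Their relative median was -0.95 (camera adjusted p = 0.00629; adjusted p = 0.325 with an estimated correlation).

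Others passed as lower than other genes in wild-caught surface livers. Lipoproteins and lipid transport gave 9 lower and 16 not passing of 25 tested (3 higher and 14 lower adjusted over the list alone), with apoc1 (-1.30 ± 0.23) and apoa2 (-2.02 ± 0.38) lower. Lipoprotein genes had a relative median of -0.97 (camera adjusted p = 0.00418; adjusted p = 0.325 with an estimated correlation). Erythrocyte and thrombocyte markers gave 5 lower and 10 not passing of 15 tested (7 lower adjusted over the list alone), with slc4a1a lower (-2.23 ± 0.39). Erythrocyte markers had a relative median of -0.78 (camera adjusted p = 0.00629; adjusted p = 0.325 with an estimated correlation). The circadian clock gave 7 lower and 36 not passing of 43 tested (7 lower adjusted over the list alone), with cry3b lower (-3.45 ± 0.53). Clock genes had a relative median of -0.44 (camera adjusted p = 0.00834; adjusted p = 0.325 with an estimated correlation). Insulin and growth factor signalling gave 1 higher, 6 lower and 27 not passing of 34 tested (1 higher and 8 lower adjusted over the list alone) and a relative median of -0.54 (camera adjusted p = 0.0131; adjusted p = 0.325 with an estimated correlation). Its member leptin, lepa, was higher at 127 ± 116 against 9.27 ± 7.86 TPM (3.68 ± 0.92), a call lost without surface wild 1 (adjusted p = 0.0717), surface wild 2 (0.0764) or surface lab 3 (0.0614).

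Hepatocyte markers gave 1 higher, 5 lower and 17 not passing of 23 tested (2 higher and 9 lower adjusted over the list alone) in wild-caught against laboratory surface livers, with a relative median of -0.50 (camera adjusted p = 0.0402; adjusted p = 0.325 with an estimated correlation). Bile acid synthesis and transport gave 1 higher, 4 lower and 12 not passing of 17 tested (1 higher and 4 lower adjusted over the list alone) and a relative median of -0.77 (camera adjusted p = 0.0402; adjusted p = 0.341 with an estimated correlation). Egg yolk precursors and oestrogen-responsive genes gave 3 lower and 5 not passing of 8 tested (4 lower adjusted over the list alone) and a relative median of -1.65 (camera adjusted p = 0.0447; adjusted p = 0.339 with an estimated correlation). Bile acid genes lost the call without surface wild 1 (adjusted p = 0.112) or surface lab 1 (0.0534), and glycolysis without surface wild 1 (0.0509). Heat shock lost it without surface wild 1 (0.107), surface wild 2 (0.120) or surface lab 3 (0.194). Yolk and oestrogen genes lost it without cave wild 1 (0.0569), surface wild 1 (0.0823), surface lab 1 (0.108) or surface lab 3 (0.188), and with the replicate number as a block (0.0612). Hepatocyte markers lost it without surface wild 2 (0.0586), surface lab 1 (0.0889) or surface lab 3 (0.166), and under median-of-ratios scaling (0.074).

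Surface livers gave 2317 genes, 873 higher and 1444 lower in wild-caught fish, at a median log2 difference of -0.11 for all genes. Median-of-ratios scaling gave 2387, 1269 higher and 1118 lower. The 6 surface libraries fitted alone gave 122, and 0 in limma with the replicate number as a block, although 4085 genes then had an unadjusted p under 0.05. The block in all 12 libraries gave 2343. Of the genes named above, hspa5 (adjusted p = 0.0799), msmo1 (0.0592), sqlea (0.0605), hyou1 (0.0751), acadm (0.0807) and apoa2 (0.0662) were among those that lost their call in the 6 libraries alone. Leaving out surface wild 1, 2 or 3 gave 882, 942 or 3616 genes, and leaving out surface lab 2 or 3 gave 1496 or 1077. Groups did not overlap for 4035 genes (31.3%, 10% by chance), and for 4490 (34.8%) with median-of-ratios scaling.

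**Figure D3:**
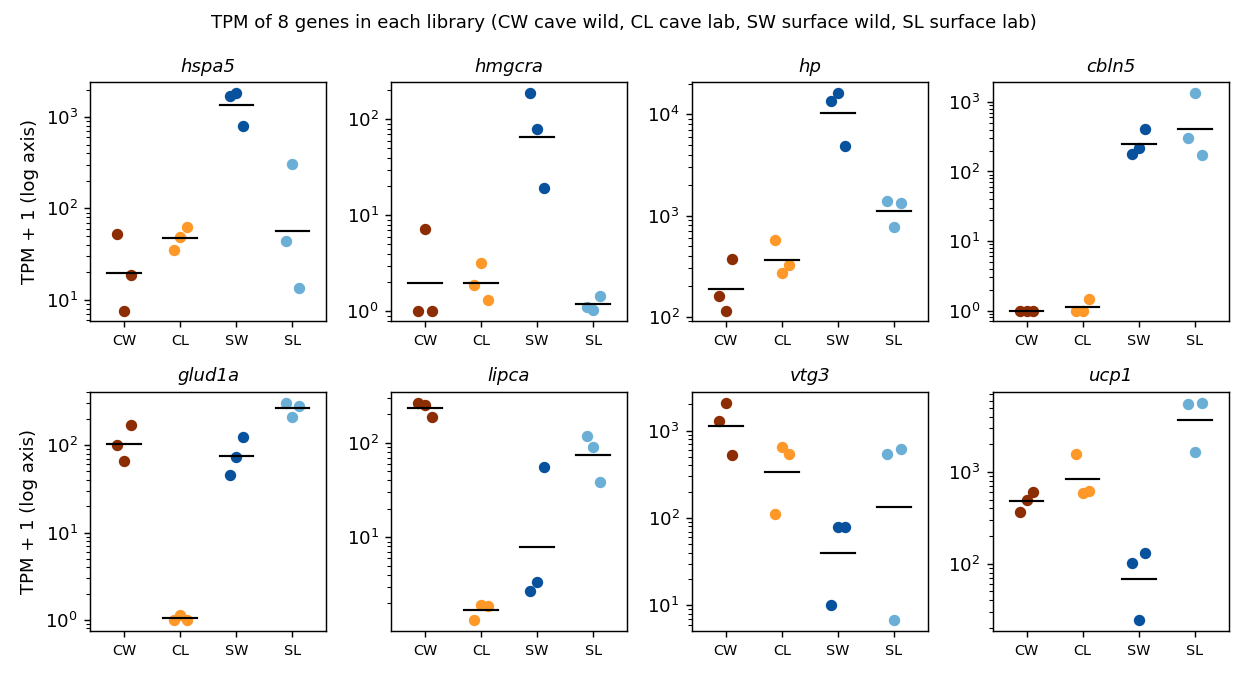
Level of 8 genes in each liver as TPM + 1 on a log axis, by group (CW cave wild, CL cave lab, SW surface wild, SL surface lab). Points are livers and bars are means on the log scale; hspa5, hmgcra and hp stand highest in surface wild livers, while glud1a is near 0 in cave lab livers alone.

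The difference between cave and surface livers was not the same in wild-caught and laboratory fish for single genes. For gene lists it differed in camera at the preset correlation alone, where 18 of 35 passed, against 0 with an estimated correlation. The interaction was largest for lipca (10.33 ± 1.27, adjusted p = 0.00277) and glud1a (8.45 ± 0.60, adjusted p = 4.9e-05), both near 0 in laboratory cave livers. In surface wild livers 1, 2 and 3 lipca also stood low in 1 and 2, at 1.67, 2.38 and 54.1 TPM, against 117, 88.7 and 37.1 in surface lab livers. The neuropilin receptor gene nrp1b (3.98 ± 0.74, adjusted p = 0.0162) and ucp1 (4.97 ± 0.93, adjusted p = 0.0171) had a positive interaction too. On the other side stood the respiratory chain subunit cox6b1 (-6.24 ± 0.98, adjusted p = 0.00897). Its level was 13.2 ± 6.56 TPM in cave wild, 64.2 ± 22.0 in cave lab, 123 ± 83.5 in surface wild and 5.78 ± 3.60 in surface lab livers. The subunit cox4i1l (-3.33 ± 0.55), the co-chaperone dnajb9b (-4.89 ± 0.89) and psmb8a (-5.14 ± 0.76, adjusted p = 0.00665) followed.

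Sterol synthesis gave 8 lower and 17 not passing of 25 tested (20 lower adjusted over the list alone) in the interaction and a relative median of -2.66 (camera adjusted p = 1.7e-05; adjusted p = 0.493 with an estimated correlation). Unfolded protein response genes gave 6 lower and 40 not passing of 46 tested (25 lower adjusted over the list alone) and a relative median of -1.62 (camera adjusted p = 5.2e-05; adjusted p = 0.594 with an estimated correlation). The interferon response gave 6 lower and 26 not passing of 32 tested (24 lower adjusted over the list alone), with psmb13a lower (-3.05 ± 0.53). Interferon genes had a relative median of -1.59 (camera adjusted p = 5.0e-06; adjusted p = 0.486 with an estimated correlation). Macrophage markers gave 8 lower and 10 not passing of 18 tested (16 lower adjusted over the list alone), with MPEG1 (-2.85 ± 0.47) and PTPRC (-2.504 ± 0.45) lower. Their relative median was -1.31 (camera adjusted p = 1.7e-05; adjusted p = 0.316 with an estimated correlation). Under median-of-ratios scaling psmb13a (adjusted p = 0.0668), MPEG1 (0.0541) and PTPRC (0.0716) lost their calls.

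Xenobiotic metabolism lay on the positive side of the interaction, with 1 higher and 26 not passing of 27 tested (0 adjusted over the list alone) and a relative median of 1.72 (camera adjusted p = 1.0e-07; adjusted p = 0.316 with an estimated correlation). Amino acid catabolism gave 2 higher, 2 lower and 68 not passing of 72 tested (3 higher and 2 lower adjusted over the list alone), with hgd higher (3.21 ± 0.56). Catabolic genes had a relative median of 0.87 (camera adjusted p = 5.7e-09; adjusted p = 0.316 with an estimated correlation). Ribosomal proteins had 0 of 81 tested passing in limma, with 1 at an unadjusted p under 0.05 (0 adjusted over the list alone) and a relative median of 0.81 (camera adjusted p = 1.6e-12; adjusted p = 0.493 with an estimated correlation). Fatty acid oxidation gave 1 lower and 42 not passing of 43 tested (1 lower adjusted over the list alone) and a relative median of 0.98 (camera adjusted p = 4.1e-05; adjusted p = 0.493 with an estimated correlation). Exocrine pancreas markers had 0 of 9 tested passing in limma, with 1 at an unadjusted p under 0.05 (0 adjusted over the list alone) and a relative median of 1.6 (camera adjusted p = 7.3e-04; adjusted p = 0.491 with an estimated correlation).

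Further lists passed on the positive side of the interaction with few or no called members. Yolk and oestrogen genes had 0 of 8 tested passing in limma, with 1 at an unadjusted p under 0.05, with a relative median of 0.96 (camera adjusted p = 0.00437; adjusted p = 0.316 with an estimated correlation). Adipocyte markers had 0 of 8 tested passing in limma, with 1 at an unadjusted p under 0.05, with 1.04 (camera adjusted p = 0.014; adjusted p = 0.316 with an estimated correlation). Hepatocyte markers had 0 of 23 tested passing in limma, with 6 at an unadjusted p under 0.05, with 0.60 (camera adjusted p = 0.00939; adjusted p = 0.316 with an estimated correlation). Lipoproteins gave 1 higher and 24 not passing of 25 tested, with 0.29 (camera adjusted p = 0.00437; adjusted p = 0.373 with an estimated correlation), and gluconeogenesis 1 higher, 2 lower and 28 not passing of 31 tested, with 0.47 (camera adjusted p = 0.00918; adjusted p = 0.407 with an estimated correlation). Oxidative phosphorylation gave 1 higher, 2 lower and 82 not passing of 85 tested, with 0.57 (camera adjusted p = 1.9e-04; adjusted p = 0.643 with an estimated correlation). Antioxidant defence gave 3 lower and 28 not passing of 31 tested, with 0.56 (camera adjusted p = 0.0251; adjusted p = 0.316 with an estimated correlation). Insulin signalling gave 1 lower and 33 not passing of 34 tested, with 0.24 (camera adjusted p = 0.0433; adjusted p = 0.493 with an estimated correlation), and bile acid genes 2 lower and 15 not passing of 17 tested, with 0.89 (camera adjusted p = 0.0471; adjusted p = 0.493 with an estimated correlation).

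On the TPM scale itself the interaction medians of lipoproteins (-0.33), gluconeogenesis (-0.14), oxidative phosphorylation (-0.05), antioxidant defence (-0.05), insulin signalling (-0.38) and hepatocyte markers (-0.01) were below 0, so their sign rests on the shift of all genes. The interaction means on that scale were 0.19, -0.14, -0.18, -0.30, -0.11 and -0.08 in the same order.

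The interaction gave 655 genes, 115 higher and 540 lower, at a median log2 difference of -0.61 for all genes. Median-of-ratios scaling gave 248, 163 higher and 85 lower. Leaving out cave wild 1, 2 or 3 gave 211, 286 or 161 genes, and cave lab 1, 2 or 3 gave 255, 268 or 249. Leaving out surface wild 1, 2 or 3 gave 316, 309 or 3035, and surface lab 1, 2 or 3 gave 257, 1147 or 250. In this test ucp1 lost its call without cave wild 3 (adjusted p = 0.0525). Bile acid genes lost their call without surface wild 1 (0.201) and 6 other libraries. Insulin signalling lost it without cave wild 2 (0.121), cave lab 2 (0.0841), cave lab 3 (0.110), surface wild 2 (0.101) or surface lab 1 (0.0946). Antioxidant defence lost its call without cave wild 1 (0.0888) or surface lab 3 (0.0527), and oxidative phosphorylation without cave wild 1 (0.0996). Under median-of-ratios scaling bile acid genes (0.13), insulin signalling (0.21) and antioxidant defence (0.073) lost theirs, and quantile scaling kept 8 of the 18 list calls.

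**Figure D4:**
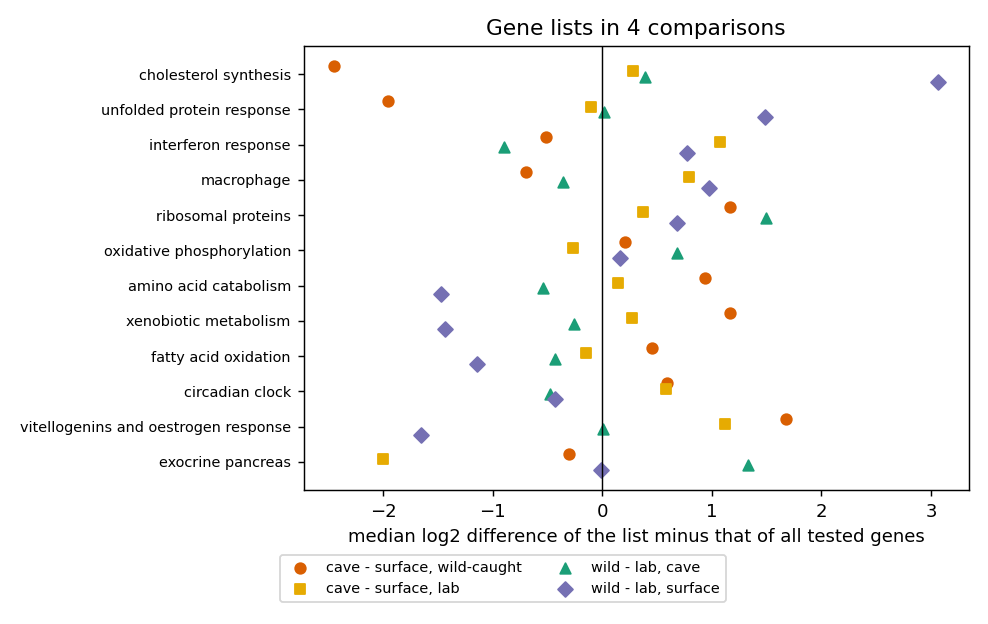
Median log2 difference of 12 gene lists minus that of all tested genes, in 4 comparisons of 2 groups. Marks stand for the comparisons; cholesterol synthesis and the unfolded protein response lie low in wild-caught cave against surface livers and high in wild-caught against laboratory surface livers.

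Differences between the forms overlapped in the 2 environments. Across tested genes the cave minus surface differences correlated at r = 0.389 (rho = 0.374) between wild-caught and laboratory fish, which share no liver, and 55.3% had the same sign. Of genes passing in both, 212 were higher in both (34.8 expected if independent), 124 lower in both (78.3) and 40 opposite (195). The wild-caught minus laboratory differences of cave and surface livers correlated at r = 0.362 (rho = 0.405), with 61.7% of the same sign. Of genes passing in both, 24 were higher in both (13.2), 766 lower in both (495) and 71 opposite (321). These overlaps and shares of sign were taken on the TPM scale and hold its shifts. The medians of all genes were -0.46 and 0.10 for the forms in wild-caught and laboratory fish. For wild-caught minus laboratory they were -0.69 in cave and -0.11 in surface fish. Median-of-ratios scaling called 504 genes lower in cave fish, fewer than these 766, and the overlap was not computed on that scale. Genes are not independent of each other, so no p is given for the correlations and overlaps.

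Only 6 genes were listed at 0 in all 6 libraries of a form and at 1 TPM or more in all 6 of the other, 3 in each direction, and none had a name. An example is ENSAMXG00000041653, at 1.23 to 16.0 TPM in cave livers, and another ENSAMXG00000030832, at 1.41 to 15.2 TPM in surface livers. No other split of the 12 libraries gave more than 2 such genes (exact p = 0.00216 over 462 splits). Of the muscle markers, 25 were in the table and 0 reached the test, the highest at 9.39 TPM in a library. Genes outside this fixed list, such as smpx at 19.7 to 33.7 TPM in cave lab livers, were not counted. The list alone therefore does not exclude muscle transcripts. Exocrine pancreas genes made up 0.220 ± 0.0657% of transcripts in cave wild, 0.138 ± 0.135% in cave lab and 0.421 ± 0.200% in surface lab livers (n = 3 each). In surface wild livers 1, 2 and 3 they made up 0.296%, 0.145% and 1.36%.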

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

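Of the tests in this part, the splits of libraries for the 5 comparisons and the vtg3 tests of sterol and unfolded protein genes were fixed before their results were seen. The split for genes present in a single form and all other tests of explanations were chosen after.

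A difference between groups drew attention to 655 genes whose cave minus surface difference was not the same in wild-caught and laboratory fish by the interaction test. The largest were lipca (10.33), glud1a (8.45), ucp1 (4.97), urahb (4.40) and nrp1b (3.98) on the positive side, and c4 (-7.27), cox6b1 (-6.24), hspa5 (-5.88), hmgcra (-5.82) and msmo1 (-5.50) on the negative side. Of these, hspa5 lost its call on leaving out any of 9 libraries (adjusted p of 0.0644 to 0.0791) and under median-of-ratios scaling (0.068), and msmo1 on leaving out any of 6 (0.0523 to 0.0732). Without cave wild 1 the calls of hmgcra (0.0610), c4 (0.0525) and urahb (0.0578) were lost, without cave wild 3 those of hmgcra (0.0624), ucp1 (0.0525) and urahb (0.0588). Without cave lab 1 that of urahb (0.0506) and without cave lab 2 that of hmgcra (0.0510) were lost. Other splits of the libraries gave as many interaction genes in 4 of 100 drawn, the real one included, with 2043 at most. The larger ones kept the real wild-caught split and mixed surface lab 1 and 2 with a cave lab liver.

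At the preset correlation alone, gene lists differed between groups too. As relative medians, cholesterol synthesis -2.66, unfolded protein response -1.62, interferon response -1.59 and macrophage markers -1.31 lay on the negative side. Metabolic lists on the positive side were xenobiotic metabolism 1.72, fatty acid oxidation 0.98, bile acid synthesis and transport 0.89 and amino acid catabolism 0.87. Smaller values were antioxidant defence 0.56, gluconeogenesis and glycogen 0.47, lipoproteins 0.29 and insulin signalling 0.24. Cell type and complex lists were exocrine pancreas 1.5995, adipocyte 1.04, vitellogenins 0.96, ribosomal proteins 0.81, hepatocyte 0.60 and oxidative phosphorylation 0.57. Before the median of all genes was subtracted, the medians of lipoproteins, gluconeogenesis, oxidative phosphorylation, antioxidant defence, insulin signalling and hepatocyte markers were below 0. With an estimated correlation 0 of the lists named here passed in camera (4 of 35 at an unadjusted p under 0.05).

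Splits of the 6 livers of a comparison into other groups of 3 gave far fewer genes than the real split, yet 10 splits are too few for a share under 0.05. The other splits also mix the real groups, so a real difference enters their residual spread and lowers their counts. The size of the gap therefore decides nothing about chance. The real and the highest other counts were 4074 and 1 for wild-caught forms, 974 and 1 for laboratory forms, 4618 and 2 for cave fish, and 2317 and 15 for surface fish, each matched by 1 split of 10, the real one. For genes present in a single form, 1 of 462 splits, the real one, gave 6, and the highest other gave 2, so a split of the livers by chance is argued against.

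Most genes called in cave fish, 4423 of 4618, were lower in wild-caught than in laboratory livers. Crowding by ribosomal protein transcripts alone is argued against, since without them 93.5% of the 2682 called genes were still lower, though lower calls went from 4423 to 2509 and the median of all genes from -0.69 to -0.52. A single scale shift of most genes in TPM stays open: 11.4% of the lower calls (504) stayed with median-of-ratios factors and the median log2 difference of all 4423 went from -1.23 (quartiles -1.58 and -0.97, median standard error 0.31) to -0.56 (-0.88 and -0.30, 0.28), but these factors centre the comparison, which fixes such a loss in advance. Whether RNA quality that favours short transcripts could produce the shift stays open, as oxidative phosphorylation genes stood at 0.68 and ribosomal protein genes at 1.49 relative to all genes, and integrity values and transcript lengths were not used here. A biological difference in cell size or total RNA between wild-caught and laboratory cave fish was not tested.

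In wild-caught against laboratory surface livers 16 of 25 sterol synthesis and 15 of 46 unfolded protein genes passed as higher, and both lists passed in camera (adjusted p = 7.7e-12 and 1.3e-11; 0.325 for each with an estimated correlation). A capture effect of equal size in both wild-caught groups is argued against. The relative medians in cave fish were 12.8% (0.39, quartiles -0.12 and 0.67) and 1.32% (0.02, quartiles -0.62 and 0.48) of those in surface fish, 3.07 and 1.49. A weaker effect of capture in cave fish cannot be excluded, as both lists also passed as higher there in camera at the preset correlation. An oestrogen response is argued against as the whole cause, since with vtg3 as a covariate 92.3% of the sterol median was kept (2.95 to 2.73, 16 genes called to 14) and 85.8% of the other (1.38 to 1.18, 15 to 11). Whether surface wild livers 1 and 2 alone carried this stays open, because a single liver is left: surface wild 3 stood 1.44 above the laboratory mean for sterol genes (22 of 25 higher) and 0.87 for unfolded protein genes (40 of 46), where libraries 1 and 2 stood at 4.46 and 3.11 and at 1.80 and 1.67. Diet, season and handling of the wild-caught surface fish were not tested.

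Of 8 tested yolk and oestrogen genes, 3 were lower in wild-caught surface than in wild-caught cave livers and 5 did not pass (camera adjusted p = 4.8e-05; adjusted p = 0.253 with an estimated correlation). The labels do not give sex. The marker vtg3 stood at 1296, 2091 and 523 TPM in cave wild livers and at 8.97, 78.3 and 78.4 TPM in surface wild livers, with no overlap. A different sex makeup stays open: with vtg3 as a covariate 141 genes were called against 4074, while the median absolute log2 difference of the 4074 went from 1.38 to 1.06 and its standard error from 0.36 to 0.48. As vtg3 and the form of the fish go together in these 6 livers, the covariate also takes up the difference between forms.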

How the results depend on the processing

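In this part the tests chosen only after seeing the data were those without surface wild libraries 1 and 2, with vtg3 as a covariate, without ribosomal protein genes, and with the replicate block in the 6 surface libraries alone. Of 345 named gene results past the threshold, 130 kept their call and sign under every alternative run for single genes. No gene result called in the main analysis or under an alternative turned its sign there. The 4 tests chosen after seeing the data are not among these alternatives. Robust eBayes kept all 391 gene results tested, and leaving out 1 library kept 4155 of 4692. Results called in neither fit count as kept here, whatever their sign. Read depth is unknown, so its limit on weakly expressed genes could not be measured. The cause of each change below was not tested, unless a smaller set of genes makes it plain.

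Counts of called genes moved with scaling. For the wild-caught forms 4074 genes became 2327 with median-of-ratios and 2025 with quantile scaling, for cave fish 4618 became 983 and 934, and for the interaction 655 became 248 and 232. The filter at 5 TPM, which tests fewer genes, gave 381 for laboratory forms (974), 2732 for cave fish and 305 for the interaction. Array weights gave 1857, 7347 and 3346 in these comparisons. Without ribosomal protein genes cave fish gave 2682. The 6 libraries compared, fitted alone, gave 1916 for wild-caught forms, 787 for laboratory forms and 122 for surface fish (2317). For cave fish the count rose to 6209 (4618), so fewer degrees of freedom alone do not account for these changes. The main fit takes the same spread per gene for all groups. Array weights, lower for libraries with more scatter, ran from 0.319 in surface wild 3 to 3.51 in cave lab 3. The replicate block in the 6 surface libraries alone gave 0 in limma (4085 at an unadjusted p under 0.05). In all 12 libraries the replicate block gave 4011, 889, 4649, 2343 and 524 genes and changed no other count by over 1.5 times. Without surface wild libraries 1 and 2, wild-caught forms gave 226, surface fish 154 and the interaction 160. With vtg3 as a covariate wild-caught forms gave 141 and the interaction 153. Genes present in a single form went from 6 to 17 when absent meant under 0.1 TPM, and to 0 when present meant 5 TPM in every library.

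Leaving out each library in turn gave 1546 to 5162 genes for wild-caught forms, 614 to 1059 for laboratory forms, 2179 to 5269 for cave fish, 882 to 3616 for surface fish and 161 to 3035 for the interaction. Genes present in a single form numbered 6 to 14. The correlation of form differences ran from 0.334 to 0.443 and that of environment differences from 0.280 to 0.403. Variance shares ran from 22.2% to 28.7% for morphotype, 25.4% to 29.8% for environment and 12.24% to 17.6% for the interaction.

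Lists passing in camera numbered 12 for wild-caught forms, 9 for laboratory forms, 8 for cave fish, 20 for surface fish and 18 for the interaction, and camera with an estimated correlation passed 0, 0, 0, 0 and 0 (4, 1, 1, 1 and 4 at an unadjusted p under 0.05). Fry passed 1 for laboratory forms, 25 for cave fish and 11 for the interaction. The filter at 5 TPM gave 5 for cave fish and 13 for surface fish, and quantile scaling 8 for the interaction. The replicate block in all 12 libraries ended the list calls of lipoproteins in laboratory forms (adjusted p = 0.0561), the unfolded protein response in cave fish (0.0565), vitellogenins in surface fish (0.0612) and bile acid genes in the interaction (0.0528). Leaving out 1 library gave 9 to 15, 7 to 13, 6 to 11, 17 to 21 and 16 to 19.

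The direction turned for 24 list results that were called in the main analysis, under the alternative or in both. Turns of results called in neither were not counted. Hepatocyte markers in cave fish turned to -0.52 with quantile scaling. The others turned in fry, which tests standardised values against 0 and not against other genes, so the shift of all genes enters it. The values given for fry are mean log2 differences, which stayed above 0 for intestine markers and bile acid genes although fry's direction was down. In wild-caught forms these were fatty acid oxidation (-0.000944) and hepatocyte markers (-0.00282). In cave fish the lipid lists were fatty acid synthesis (-1.07), cholesterol synthesis (-0.35), lipoproteins (-0.79) and lipid droplets (-0.91). Others there were glycolysis (-0.58), xenobiotic metabolism (-0.92), antioxidant defence (-0.82), heat shock (-0.11), unfolded protein response (-0.69), cell cycle (-0.20) and oxidative phosphorylation (-0.0436). Markers there were hepatocyte (-0.68), cholangiocyte (-0.53) and intestine (0.17). In the interaction they were bile acid genes (0.0313), gluconeogenesis (-0.14), insulin signalling (-0.11), circadian clock (-0.63), antioxidant defence (-0.30), oxidative phosphorylation (-0.18) and hepatocyte markers (-0.0847).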

Other observations

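Tests in this part are those of the comparisons above, and the paralog pairs were chosen only after the values of glud1a and hpdb were seen.

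For 2 genes that were nearly off in some groups, glud1a and hpdb, a paralog was looked at. Beside glud1a, at 111 ± 52.0 TPM in cave wild, 0.0467 ± 0.0808 in cave lab, 80.1 ± 40.2 in surface wild and 264 ± 49.4 in surface lab livers, its paralog glud1b stood at 327 ± 39.99, 572 ± 37.0, 161 ± 74.3 and 662 ± 257 TPM in the same order. Both encode glutamate dehydrogenase, which links glutamate to the citric acid cycle. Beside hpdb, at 150.1 ± 25.3 TPM in cave lab livers and listed at 0 in surface wild livers, hpda stood at 3375 ± 767, 3879 ± 704, 2893 ± 1886 and 5544 ± 319 TPM. Both encode the dioxygenase that acts early in tyrosine breakdown. How reads were shared between these paralogs is not given in the sources used here.

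Stored lipid and fat synthesis genes had few called members in wild-caught cave against surface livers. Lipid droplets and lipolysis gave 4 lower and 11 not passing of 15 tested (4 lower adjusted over the list alone), with bscl2l (-1.44 ± 0.34) lower, and fatty acid and triglyceride synthesis gave 4 lower and 29 not passing of 33 tested (2 lower adjusted over the list alone), with elovl1b (-1.67 ± 0.34) lower. Cholangiocyte markers gave 2 lower and 11 not passing of 13 tested (2 lower adjusted over the list alone), stellate cell markers 1 lower and 14 not passing of 15 tested (1 lower adjusted over the list alone) and intestine markers 2 higher and 4 not passing of 6 tested (2 higher adjusted over the list alone). Endothelial markers had 0 of 19 tested passing in limma, with 3 at an unadjusted p under 0.05 (0 adjusted over the list alone). In wild-caught against laboratory cave livers endothelial markers gave 9 lower and 10 not passing of 19 tested (10 lower adjusted over the list alone), with esama lower (-1.403 ± 0.21). There stellate cell markers gave 8 lower and 7 not passing of 15 tested (9 lower adjusted over the list alone), with fn1b lower (-2.495 ± 0.34). Under median-of-ratios scaling 1 of each stayed lower. Lists with fewer than 5 tested genes were T and NK cell (1), B and plasma cell (3), endocrine pancreas (4) and gonad (3), and no list test was run for them.

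In laboratory fish vtg3 stood at 109, 653 and 539 TPM in cave livers and at 543, 5.80 and 620 TPM in surface livers.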
